A study of Mus musculus with 6 samples.

How the data were processed

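RNA from sorted splenic CD4 T cells was extracted with TRIzol and made into libraries with a NEBNext Ultra kit, per the labels' protocols. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 1.6.0 were used with the GRCm38 build; their settings, the annotation release and any strand setting are not given in the sources used here. The authors deposited one table of FPKM values, with 1 column per library and 28914 genes by Ensembl identifier. Every identifier was matched to GENCODE M21 (GRCm38) for names and positions. No gene was at 0 in all 6 libraries.

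The unit was examined from the values. With gene length taken as the median genomic span of a gene's annotated transcripts, introns included, 100.0% of the values above 0 in each library were whole reads within 0.01, and the reads summed exactly to the library total that made them whole. With merged exon length 21.2 to 22.9% were whole. The deposited FPKM therefore divide by this span, which is 3.07 times exon length at the median of protein-coding genes and shorter than exon length in 2062 of 16778, Top2a and Socs3 among them. This understates genes with long introns relative to other genes, overstates those with a span under exon length, and so acts on the filter and the pseudocount, but not on the ratio of 1 gene between libraries. The recovered totals were 17782999, 15259455, 17799091, 17731878, 15254255 and 14958458 reads, in the order WT, CKO and BTg with replicate 1 before 2.

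Groups were taken from the sample titles, and replicate numbers from the column name in brackets in each title. Outside the brackets both BTg titles end in number 1. The number 2 of the other BTg library therefore rests on its column name alone. The design was fixed before the data were examined. Values were transformed to log2(FPKM + 1), genes with at least 1 FPKM in at least 2 libraries were kept, and all 6 libraries entered one limma fit (R 4.3.3, limma 3.58.1; lmFit, eBayes with a trend) without a block, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A fold change on this scale understates the change of low genes. With 2 libraries against 2, an exact permutation test of a single value cannot go below 0.333 (two-sided), so no such test is given. Of 37 gene lists fixed beforehand, 36 had at least 3 measured members. They cover T cell states, signalling, metabolism, chromatin and markers of other cell types, and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks only whether a list's genes move one way on balance. With an estimated correlation camera uses only the 3 residual degrees of freedom of the fit. A call can then be lost even where the estimate is below the preset value.

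The named genes followed a rule set beforehand. It takes Prdm1, up to 12 genes per direction past the threshold with non-overlapping libraries and a higher group mean of at least 2 FPKM, or where none passes the 5 smallest p per direction, up to 4 members per list past the threshold, and a fixed set that includes Il21, Il21r, Il10, Il2, Ifng, Bcl6, Foxp3, Tcf7, Ccr7, Cxcr5 and Icos. Predicted genes, immunoglobulin and T cell receptor segments and pseudogenes are counted and not named. Other genes are said to be chosen after their values were seen. Hba-a1, mt-Co1, Fos, Jun, Cd4, Ighm, Ngp and Xist were first taken as further genes of the comparisons; after some of their differences were seen to turn sign under alternatives they were withdrawn, and are given as values per library or not at all.

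The fit was tested on simulated data drawn from the real gene means and from a within-group spread moved partway to its trend with level, with 200 changed genes among 10743 tested. The changed genes had a mean level equivalent to at least 2 FPKM, and the change was made on the FPKM + 1 scale. The shares recovered therefore do not cover lower genes. For the simulated CKO against WT it recovered 0 of 34 genes changed 2-fold, 17 of 33 changed 4-fold and 32 of 33 changed 16-fold, and called 4 unchanged genes among 53 calls. For the simulated BTg against WT it recovered 1 of 33, 24 of 34 and 33 of 33, with 11 unchanged genes among 70 calls. Both shares of false calls exceeded the nominal 0.05. A list shifted in the simulated BTg was called, and 0 of the other 34 were. Genes were drawn independently there, while members of a real list can be correlated. The simulation therefore cannot show how often the preset correlation gives false list calls in the real data. Alternatives were other pseudocounts and filters, rescaling, quantile normalization, median centring, a replicate block, other variance models and leaving out each library. Limma voom on the recovered reads with at least 10 reads in 2 libraries, exon length in place of the deposited length, and leaving out CKO replicate 1 together with a block were added after seeing the data. Figures were drawn with matplotlib 3.10.9.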

Results

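Gene expression was measured by RNA sequencing in total CD4 T cells sorted from the spleens of 12-week-old NOD mice, a strain that develops autoimmune diabetes spontaneously. The cells received no further stimulation through the T cell receptor. The 6 libraries fall into 3 groups of 2, which are controls (WT), cells labelled deficient in Blimp-1 (CKO) and cells labelled as overexpressing it (BTg). Blimp-1, the product of Prdm1, is a zinc-finger transcriptional repressor. The series title concerns Blimp-1, interleukin-21 and autoimmunity, so the comparisons ask which transcripts differ when Blimp-1 is reduced or raised. The libraries held between 14958458 and 17799091 reads counted on genes. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure only the spread between these libraries.

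Prdm1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501 on GRCm38, minus strand) was measured first as a check of the labels. In WT it stood at 0.458 and 0.628 FPKM, from 171 and 201 reads. In BTg it stood at 19.6 and 30.1 FPKM, from 6275 and 9443 reads, and it rose against WT by 4.04 (SE 0.26) on the log2(FPKM + 1) scale, with limma adjusted p = 0.0221. In CKO it was not lower than in WT, at 0.849 and 0.669 FPKM from 317 and 249 reads, a log2 difference of 0.19 (SE 0.26) with limma adjusted p = 1. The values are sums over the whole gene, and the labels do not name the deleted exons, so reads from exons left in place would be counted and the level cannot check a deletion of part of the gene. The libraries are therefore called the libraries labelled CKO, and every direction drawn from them rests on the label.

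**Figure D1:**
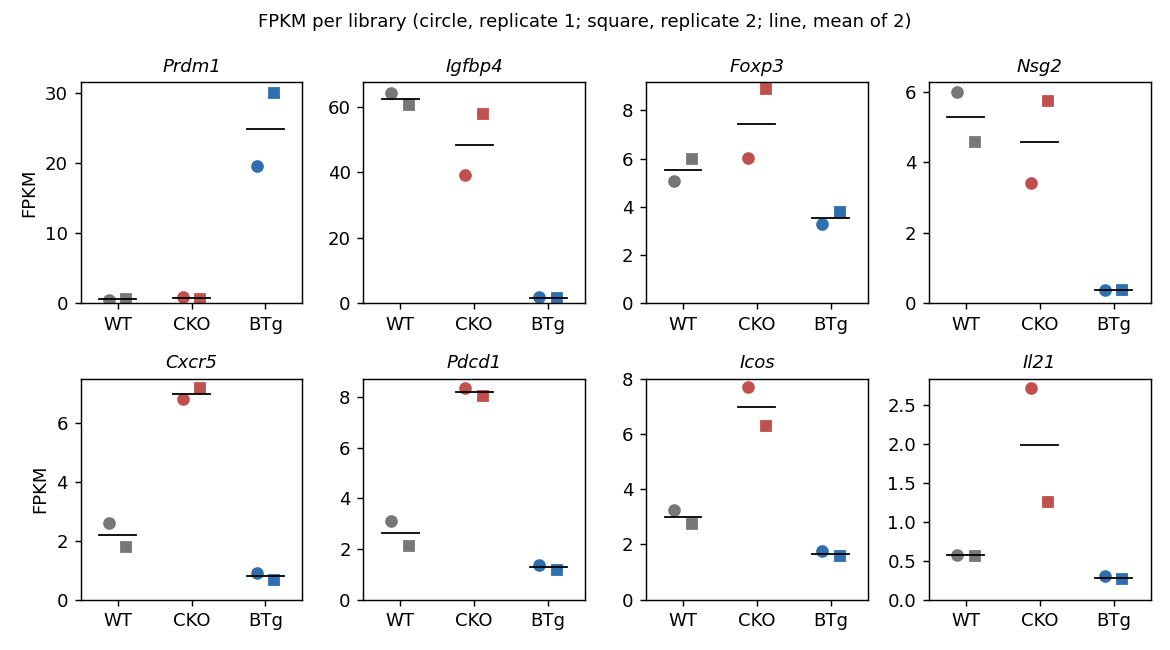
FPKM of 8 genes in each of the 6 libraries, one panel per gene, with circles for replicate 1, squares for replicate 2 and a line at the mean of 2; every axis starts at 0. Prdm1 is high in BTg alone, Igfbp4 and Nsg2 are low in BTg, and Cxcr5, Pdcd1, Icos and Il21 are higher in both libraries labelled CKO than in any other library.

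The libraries labelled CKO carried more transcript of genes of T follicular helper (Tfh) cells, the CD4 T cells that help B cells in germinal centres. Of the 20 measured Tfh genes, 17 were higher than in WT, with a median log2 difference of 0.75, and 12 rose at adjusted p under 0.05 adjusted over the list alone; 0 passed over all genes tested. Cxcr5, the receptor that guides cells to B cell follicles, stood at 2.2 ± 0.582 FPKM in WT and 7 ± 0.258 in CKO (mean ± SD, n = 2). Pdcd1, encoding PD-1, stood at 2.63 ± 0.702 and 8.2 ± 0.238 FPKM, and Icos, a costimulatory receptor, at 2.99 ± 0.343 and 6.99 ± 0.992 FPKM. Il21 itself had 0.576 and 0.562 FPKM in WT against 2.72 and 1.26 in CKO, and Bcl6, the transcriptional repressor central to Tfh cells, 1.38 ± 0.303 against 2.62 ± 0.289 FPKM. Cebpa and Sostdc1, chosen after their values were seen, are also among the 12. They stood higher in CKO replicate 1, at 31 and 3.01 FPKM, than in replicate 2, at 10.9 and 1.01. Whether cells other than T cells gave these reads was not tested. The Tfh list was called by camera (adjusted p = 2.4e-13), a call lost with an estimated correlation (adjusted p = 0.139). The estimate was 0.0033, under the preset 0.01, so correlation between members does not account for this loss. For the cell cycle and neutrophil lists it was 0.90 and 0.99. Fry called the Tfh list (adjusted p = 0.0127), but not with limma voom on recovered reads (fry adjusted p = 0.176). Its median was 0.76 between the libraries numbered 1 and 0.65 between those numbered 2.

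No single gene passed in this comparison: of 10798 genes, 0 had limma adjusted p under 0.05 and 454 had unadjusted p under 0.05, 336 of them higher and 118 lower in CKO. limma voom on reads recovered from the FPKM values called 0 of 15927, with 866 at unadjusted p under 0.05. Without CKO replicate 2 the count was 81, which leaves CKO replicate 1 alone in its group, and without a filter on low values it was 65, none of them changed by 2-fold on this scale. The genes with the smallest p that the naming rule takes did not pass the threshold. Those higher in CKO were Ces2c, Cdk5r1, Pdcd1, Mir3058 and Cxcr5, with log2 differences of 1.27, 1.28, 1.36, 1.66 and 1.34 in that order and adjusted p = 0.535 for each. Those lower were Mir7647, Mir5119, Scarna2, Ampd1 and Adh1, with log2 differences of -1.85, -0.66, -0.99, -0.81 and -0.93, and adjusted p = 0.974 for Mir7647 and 1 for each of the others. Mir3058 had 0 and 0 reads in WT and 3 and 4 in CKO, Mir7647 5 and 5 reads in WT and 2 and 0 in CKO, and Mir5119 4 and 3 reads in WT and 2 and 2 in CKO, too few reads for limma voom, so their differences rest on single reads. The 3 Mir genes lie inside Nudt4, Diablo and Cdk12, Cxcr5 overlaps Bcl9l, and Adh1, Ampd1, Anxa2, Bcl6, Bhlhe40, Ccr9, Eomes, Foxp3, Gzmk, Icos, Ifng, Il2, Il4ra, Mki67, Satb1, Tcf7 and Top2a overlap other genes, so how reads were divided between them is uncertain.

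Coinhibitory receptor genes were higher in CKO, in 7 of 10 members, and 4 rose adjusted over the list alone (camera adjusted p = 9.6e-06; adjusted p = 0.309 with an estimated correlation). Besides Pdcd1, these included Tigit, with a log2 difference of 1.14 (SE 0.20), and Lag3, with 1.35 (SE 0.24); both were chosen after their values were seen. The lists are not separate evidence: 7 of 10 coinhibitory, 11 of 20 Tfh and 11 of 13 type 1 helper members stand in another list too, and Pdcd1 and Cd200 are counted as rising in both the Tfh and the coinhibitory list. Effector and memory genes were higher in 25 of 28, with a median of 0.66 (camera adjusted p = 3.3e-12; adjusted p = 0.189 with an estimated correlation). In that list 4 members rose adjusted over the list alone, all chosen after their values were seen. Cxcr3, a chemokine receptor of type 1 helper cells, stood at 13.3 ± 0.343 FPKM in WT and 33.3 ± 7.05 in CKO. S100a6, Bhlhe40 and Anxa2 stood higher in CKO replicate 1, at 194, 26.8 and 15 FPKM, than in replicate 2, at 72.2, 10.2 and 5.25. Genes of naive and quiescent T cells were lower in 21 of 23, with a median of -0.50 (camera adjusted p = 3.6e-09; adjusted p = 0.343 with an estimated correlation), and 0 members fell adjusted over the list alone. Ccr7, which directs naive cells to lymph nodes, was 10.5 FPKM in CKO replicate 1 and 26.2 in replicate 2, against 39.6 ± 6.11 in WT. Tcf7, a transcription factor of naive and memory T cells, was 17.5 and 34 FPKM, against 34.6 ± 1.46 in WT. The naive list's median was -0.90 between the libraries numbered 1 and -0.15 between those numbered 2.

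The regulatory T cell list had 13 of 17 members higher (camera adjusted p = 3.3e-05; adjusted p = 0.343 with an estimated correlation), and Foxp3, its defining transcription factor, stood at 5.53 ± 0.651 FPKM in WT and 7.45 ± 2.02 in CKO. The type 1 and type 17 helper lists had 11 of 13 and 9 of 10 members higher, with camera adjusted p = 2.4e-04 and 8.4e-06, and adjusted p = 0.343 and 0.189 with an estimated correlation. Adjusted over the list alone, 1 regulatory T cell, 1 type 1 helper and 0 type 17 helper members rose. All 36 cell cycle genes were higher in the group mean, yet 0 rose adjusted over the list alone, and the median was 1.71 between libraries numbered 1 and -0.18 between those numbered 2 (camera adjusted p = 1.8e-13; adjusted p = 0.395 with an estimated correlation). Mki67, a proliferation marker, was 4.96 and 28.3 FPKM in WT and 30 and 26 in CKO. In all, 20 of 36 lists were called with the preset correlation, 18 higher and 2 lower, and 0 with an estimated one. The 2 lower ones were the naive list and the ribosomal protein list, with a median of -0.33 for the latter, whose direction turned without WT replicate 1 (mean log2 difference 0.11) and whose call ended without CKO replicate 2 (-0.05). The type 1 helper call ended without WT replicate 2 (mean 0.43).

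Markers of other cell types were also higher in CKO, most of all in 1 library. CKO replicate 1 stood apart on the first principal component, which held 56.5% of the variance. Genes of 6 neutrophil granule and calcium-binding proteins took 0.908% of its reads, against 0.0159% in CKO replicate 2 and at most 0.00988% elsewhere. Immunoglobulin segments took 6.99% of its reads, 1.8% in CKO replicate 2 and 0.704 to 1.17% in the other groups. S100a8 reached 3612 FPKM in CKO replicate 1 and 43.8 in replicate 2, and Cd4 was 53.8 and 93.7 FPKM. Each gene was chosen after its values were seen. The neutrophil, plasma cell, B cell, monocyte and basophil lists were all called higher in CKO, with medians of 3.37, 1.91, 0.85, 1.22 and 2.81; each had adjusted p = 0.343 with an estimated correlation. Between the libraries numbered 2 these 5 medians were 0.35, 0.67, -0.01, 0.17 and 0.78. Without CKO replicate 1 they were 1.09, 0.84, 0.20, 0.36 and 1.16, each smaller than with it. The Tfh median without that library was 0.61 and 5 members rose adjusted over the list alone (adjusted p = 0.249 with an estimated correlation).

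**Figure D2:**
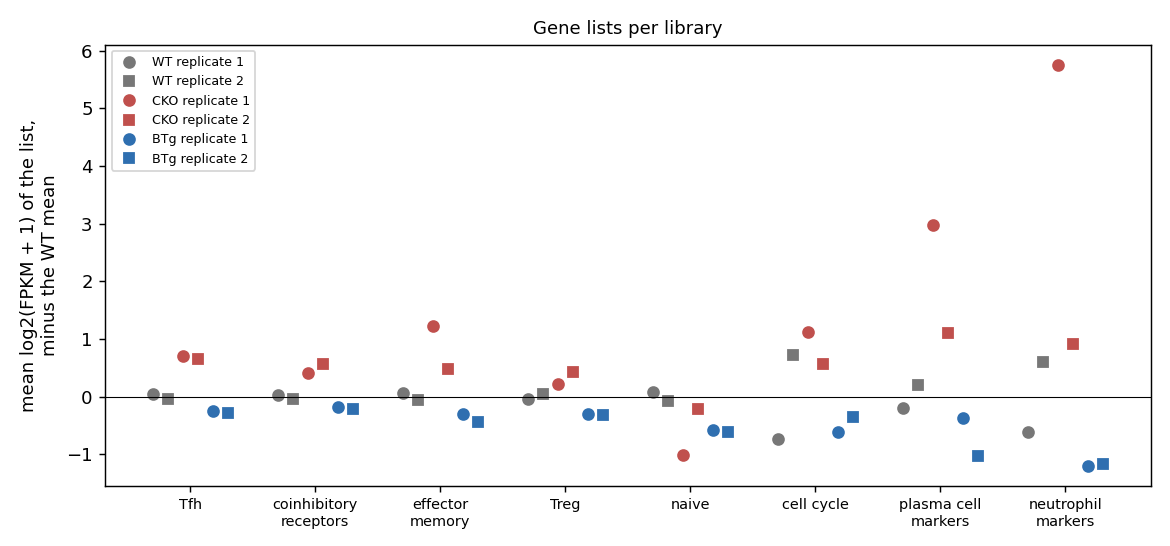
Mean log2(FPKM + 1) of the measured members of 8 gene lists in each library, minus the WT mean; circles are replicate 1 and squares replicate 2, grey WT, red CKO and blue BTg. Both libraries labelled CKO lie above both WT and both BTg libraries in the Tfh list, while in the neutrophil list CKO replicate 1 lies far above every other library.

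In BTg against WT, 2 of 10798 genes passed in the fit without a block, and 0 passed with a replicate block. Prdm1 rose, as given above, and Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392 on GRCm38), a binding protein of insulin-like growth factors, fell from 62.5 ± 2.73 FPKM in WT to 1.67 ± 0.275 in BTg (mean ± SD, n = 2). Its log2 change was -4.57 (SE 0.29) with limma adjusted p = 0.0221. Igfbp4 belongs to the naive list, in which 5 of 23 members fell adjusted over the list alone. Nsg2 and Dapl1, chosen after their values were seen, were among them, with log2 changes of -2.19 (SE 0.27) and -2.06 (SE 0.46); Dapl1 was listed at 0 and 0.00328 FPKM in BTg.

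The naive list was split in BTg, with 13 members higher and 10 lower, so that the median was 0.11 while the mean was -0.59 and camera called it lower (adjusted p = 4.2e-05; adjusted p = 0.617 with an estimated correlation). Tcf7 stood at 34.6 ± 1.46 FPKM in WT and 36.2 ± 0.814 in BTg, and Ccr7 at 39.6 ± 6.11 and 24.8 ± 0.311, neither past the threshold. Tfh genes were lower in 17 of 20, with a median of -0.20 (camera adjusted p = 1.1e-06; adjusted p = 0.309 with an estimated correlation), and 0 fell adjusted over the list alone. Cxcr5 had a log2 difference of -0.82 (SE 0.22), Icos -0.58 (SE 0.20), Bcl6 -0.19 (SE 0.21) and Il21 -0.29 (SE 0.29), none of them past the threshold. Regulatory T cell genes were lower in 15 of 17 (camera adjusted p = 3.3e-08; adjusted p = 0.309 with an estimated correlation), and effector and memory genes in 23 of 28 (camera adjusted p = 5.0e-07; adjusted p = 0.309 with an estimated correlation). In both lists 0 members fell adjusted over the list alone. Foxp3 was 5.53 ± 0.651 FPKM in WT and 3.54 ± 0.378 in BTg, and Ifng 0.644 ± 0.304 and 0.216 ± 0.0116, neither gene past the threshold. Without WT replicate 1 the naive, Tfh and effector lists were no longer called, at mean log2 differences of -0.51, -0.22 and -0.32.

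The receptor for interleukin-21, Il21r, was 9.03 and 10.6 FPKM in BTg against 5.45 and 6.11 in WT, a log2 difference of 0.67 (SE 0.29) with adjusted p = 1, not past the threshold. Socs3, a feedback inhibitor of cytokine signalling, and Il4ra, a receptor chain for interleukin-4, both chosen after their values were seen, had log2 differences of 0.81 (SE 0.29) and 0.77 (SE 0.32), also not past it. Il7r, the interleukin-7 receptor chain, chosen likewise, was lower, at 22.7 ± 4.8 FPKM in WT and 9.05 ± 0.932 in BTg, a log2 difference of -1.23 (SE 0.38) that did not pass. As a whole the list for interleukin-21 and common gamma chain signalling had 10 members higher and 12 lower and was not called (camera adjusted p = 0.692). In all, 21 of 36 lists were called, 2 higher and 19 lower, and 0 with an estimated correlation. The higher ones were immediate early and stress genes, with a median of 0.23, and proximal T cell receptor signalling genes, with 0.16. Neither was called without WT replicate 2, at mean log2 differences of 0.28 and 0.16, or without BTg replicate 1, at 0.14 and 0.20. Lists of chromatin modifiers (camera adjusted p = 0.213) and interferon response genes (camera adjusted p = 0.649) were not called. Cell cycle genes were lower in 36 of 36 in the group mean, with medians of 0.10 and -1.08 between libraries numbered 1 and 2, and the direction turned without WT replicate 2 (mean 0.24).

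Markers of other cell types were lower in BTg beside these lists, in 12 of 12 erythroid, 11 of 11 neutrophil, 11 of 11 plasma cell and 9 of 9 B cell genes. Their camera adjusted p = 1.1e-06, 0.00222, 5.4e-04 and 0.0152, and adjusted p = 0.527, 0.699, 0.617 and 0.617 with an estimated correlation. In each of these lists 0 members fell adjusted over the list alone. The erythroid median was 0.13 between libraries numbered 1 and -1.69 between those numbered 2. Without WT replicate 2 the erythroid direction turned (mean 0.32) and the neutrophil and B cell calls ended (-0.58 and -0.03). The B cell call also ended without BTg replicate 1 (-0.24) or BTg replicate 2 (-0.26), and the plasma cell call without BTg replicate 2 (-0.37).

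Leaving out any 1 of the 6 libraries, the count in this comparison was 0 by limma, against 175 genes at unadjusted p under 0.05 and 2 called by limma voom with all libraries. The log2 difference of Prdm1 was then 3.74 to 4.33, with adjusted p = 0.0694 to 0.54, and over all alternatives adjusted p = 0.00761 to 0.54.

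BTg against the libraries labelled CKO sets high Blimp-1 against its labelled absence and does not use the WT libraries for its fold changes. Again 2 of 10798 genes passed, Prdm1 higher in BTg by 3.85 (SE 0.26) (limma adjusted p = 0.0363) and Igfbp4 lower, with -4.19 (SE 0.29) (limma adjusted p = 0.0363). With a replicate block 0 passed. Tfh genes showed their widest gap here: 16 of 20 were lower in BTg, with a median of -0.97, and 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.3e-12; adjusted p = 0.154 with an estimated correlation). Cxcr5 fell from 7 ± 0.258 to 0.8 ± 0.162 FPKM by that criterion, a log2 change of -2.16 (SE 0.22) with adjusted p = 0.11 over all genes and 8.8e-04 adjusted over the list alone. Icos, Il21 and Bcl6 fell likewise, with log2 changes of -1.58 (SE 0.20), -1.17 (SE 0.29) and -0.80 (SE 0.21), adjusted over the list alone at 0.00159, 0.0144 and 0.0144. Of the coinhibitory receptors 4 of 10 fell adjusted over the list alone, including Pdcd1, Lag3 and Tigit, with log2 changes of -2.01 (SE 0.22), -1.70 (SE 0.24) and -1.48 (SE 0.20) (camera adjusted p = 1.2e-05; adjusted p = 0.253 with an estimated correlation).

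Regulatory T cell genes fell in 7 of 17 members adjusted over the list alone, with Foxp3 at 7.45 ± 2.02 FPKM in CKO and 3.54 ± 0.378 in BTg (camera adjusted p = 1.5e-08; adjusted p = 0.253 with an estimated correlation). Effector and memory genes fell in 11 of 28 (camera adjusted p = 6.8e-14; adjusted p = 0.162 with an estimated correlation). Cxcr3 fell by 4.54-fold on the FPKM + 1 scale and Ccr4, a receptor of type 2 helper cells, by 2.9-fold. The naive list split again: 5 members fell and 2 rose adjusted over the list alone. Those that fell included Igfbp4, Nsg2 and Treml2, with log2 changes of -4.19, -1.99 and -1.59, and those that rose included Ccr9 and Satb1, with 1.29 and 1.30. Satb1 encodes a chromatin organiser of T cells, and apart from Igfbp4 these genes were chosen after their values were seen. Among the markers of other cells, 10 of 11 neutrophil and 10 of 11 plasma cell genes also fell adjusted over the list alone. Without CKO replicate 1, 11 Tfh and 6 regulatory T cell members fell by that criterion, as did 9 neutrophil and 5 plasma cell members, with medians of -2.05 and -1.27. By limma 0 genes then passed over all genes tested, with 520 at unadjusted p under 0.05. The Prdm1 call was likewise lost without WT replicate 1, WT replicate 2, BTg replicate 1 or BTg replicate 2, with adjusted p = 0.0124 to 0.419 over all alternatives; without CKO replicate 2 the count was 255. By limma voom on recovered reads it was 5.

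To ask whether genes moved in opposite directions with labelled loss and with gain of Blimp-1, the fold changes of both comparisons against WT were set side by side. Their Pearson correlation across 10798 genes, which are not independent replicates, was -0.178 (Spearman's rho -0.263), where 0.5 came from 100 simulations of unchanged groups sharing the same WT libraries. The covariance was -0.0282, against 0.0698 in the simulations, a difference of -0.0979. With an effect shared by replicate number taken out of the spread, the simulated covariance was 0.0379. These simulations gave every library the same spread per gene, pooled over all groups with CKO replicate 1 included. The simulated correlation of 0.5 follows from that setting. Without CKO replicate 1, and with no number effect taken out, the covariance was 0.0184 against 0.0458 simulated. The 2 WT libraries are too few to split. The correlation was above 0 without CKO replicate 1, WT replicate 1 or WT replicate 2, at 0.146, 0.0902 and 0.313, where simulated unchanged groups gave 0.411, 0.669 and 0.667. With the number effect taken out, the covariance was 0.00653 against 0.0801 simulated without WT replicate 1, 0.0119 against 0.0171 without CKO replicate 1, -0.0682 against 0.0173 without CKO replicate 2, 0.00197 against 0.0505 without BTg replicate 1 and -0.0583 against 0.0502 without BTg replicate 2. Without WT replicate 2 it was above the simulated value, at 0.134 against 0.0798. The simulations with a number effect or a library left out were added after seeing the data, and all draw genes independently. No gene passed in both comparisons. At unadjusted p under 0.05, 15 genes were higher in CKO and lower in BTg, where independent lists would share 2.86 and the simulations gave 1.72, and 3 were lower in CKO and higher in BTg, with 0.907 and 1.39. Moving the same way, 15 were higher in both, with 2.58 and 65.7, and 14 lower in both, with 1 and 66.7; these simulated counts assume no number effect.

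**Figure D3:**
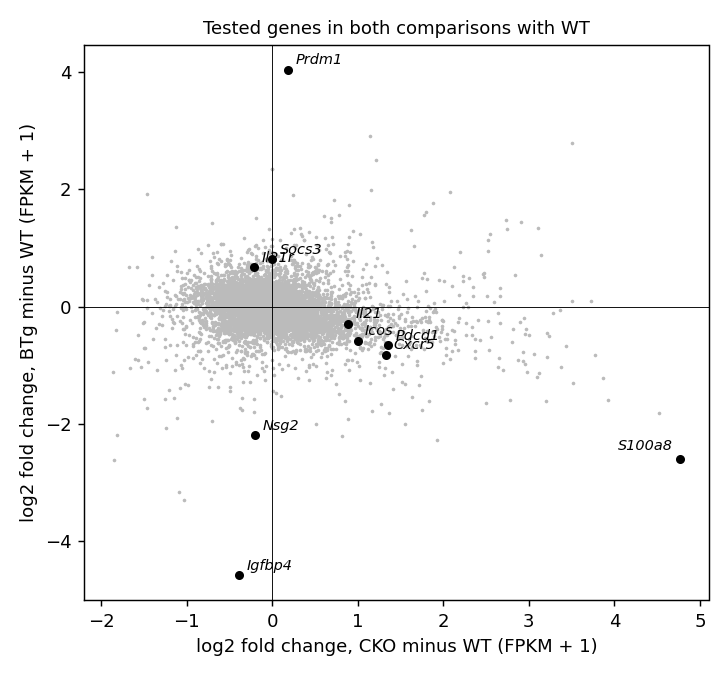
Log2 fold change on the FPKM + 1 scale of each tested gene in CKO minus WT (horizontal) and BTg minus WT (vertical), with 10 named genes in black. Prdm1 lies at 0.19 and 4.04, Igfbp4 is the lowest of the named genes on the vertical axis, and Cxcr5, Pdcd1 and Icos lie to the right of 0 and below it.

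Il10 and Il2 did not reach the FPKM filter and were not tested. Il10 had between 2 and 11 reads per library and Il2 between 1 and 8, so a difference was not detectable at this depth. Median, mean and test direction differed in sign, besides the naive list, in lists that camera did not call. These were genes next to Prdm1 in both comparisons with CKO, and dendritic cell and type 2 helper genes in BTg against WT. In BTg against CKO they were apoptosis and ribosomal protein genes. The apoptosis list, with 10 members higher and 9 lower there, was called lower by fry (adjusted p = 0.0253). That call was lost with limma voom on recovered reads (fry adjusted p = 0.781).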

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

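The alternatives on recovered reads, on exon length, and without CKO replicate 1 together with a block were chosen after seeing the data. Counts of changed genes are given for CKO against WT, BTg against WT and BTg against CKO in that order, where the main counts were 0, 2 and 2. They were 65, 46 and 81 without a filter, 0, 1 and 5 at a mean of at least 5 FPKM, 0, 0 and 0 rescaled to a common sum, 0, 0 and 0 after quantile normalization, 0, 0 and 0 in fits of the 4 libraries compared, 0, 2 and 0 with array weights, 0, 2 and 5 with voom on recovered reads, 0, 2 and 0 with voom without CKO replicate 1, 0, 2 and 9 per exon length and 0, 2 and 3 without the variance trend. Leaving out 1 library gave 0 to 81, 0 to 0 and 0 to 255. The lone library of a group is then assumed to vary like the others, and the highest counts came without CKO replicate 2. The cause was not tested. Requiring 2-fold gave 0, 2 and 2, and adjusted p under 0.1 gave 0, 2 and 2. Rescaling to a common sum moved the median log2 fold change of all genes to -0.13, 0.12 and 0.26, from -0.0287, 0.0222 and 0.0591.

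The replicate numbers are shared across groups, but 2 numbers are too few to show that they pair libraries. Deviations of same-numbered libraries correlated at 0.173, 0.469 and 0.456 across genes. With a replicate block the counts were 0, 0 and 0, with voom and a replicate block 0, 0 and 0, and without CKO replicate 1 and with a replicate block 0, 0 and 0. The Prdm1 log2 change with the replicate block was 4.04 and 3.85 against WT and CKO, past the threshold in neither, 5.48 and 5.03 with voom and the block, and 4.04 and 4.11 without CKO replicate 1 and with the block, where Prdm1 in CKO against WT was -0.0724, a turned sign.

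Prdm1 in BTg kept its direction in all settings but missed the threshold in some. Against WT its log2 change there was 4.04 at a mean of at least 5 FPKM, 5.03 rescaled, 4.12 with quantile normalization, 4.04 with 4 libraries and 3.74 to 4.33 leaving out 1 library. Against CKO it was 4.77 rescaled, 3.94 with quantile normalization, 3.85 with 4 libraries, 3.85 with array weights, 5.35 with voom without CKO replicate 1 and 3.55 to 4.15 leaving out 1 library. Called lists, 20, 21 and 22, became 13 for CKO against WT and 14 for BTg against CKO at a mean of at least 5 FPKM, 0, 0 and 0 with an estimated correlation, 3, 0 and 7 with fry, and 13 to 22 for BTg against WT leaving out 1 library. In CKO against WT fry called the Tfh, type 17 helper and CD8 T cell lists. In BTg against CKO they were the Tfh, type 17 helper, regulatory T cell, effector and memory, coinhibitory, CD8 T cell and apoptosis lists. With voom, fry kept the Tfh call in BTg against CKO (adjusted p = 0.041) but not in CKO against WT (adjusted p = 0.176). Both Tfh calls were lost with the replicate block (fry adjusted p = 0.054 and 0.0775). The correlation of both comparisons with WT was -0.296 to 0.313 leaving out 1 library and 0.106 without CKO replicate 1 and with a block; having no replicates, it was judged by the SD of its leave-one-out values, a choice made after seeing the data. Genes called in both numbered 17 without a filter and 0 otherwise.

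These results turned direction, with the cause not tested; a list's direction is camera's, relative to other genes, so it can turn while the mean keeps its sign. In CKO against WT, Il21r was -0.55 to 0.13 and Mki67 -0.0196 to 2.28 leaving out 1 library, Il21r 0.0449 without CKO replicate 1 and with a block, and Socs3 -0.10 rescaled, -0.28 with quantile normalization, -0.0097 centred, -0.00177 with voom and a block, -0.19 with voom without CKO replicate 1 and -0.0137 to 0.0143 leaving out 1 library. Mean log2 changes at a mean of at least 5 FPKM were -0.13 for chemokine and adhesion receptors and -0.16 for cytokines, and for cytokines 0.01002 in BTg against WT and 0.17 in BTg against CKO. Ribosomal protein genes ranged over -0.77 to 0.11 in CKO against WT and -0.75 to 0.13 in BTg against WT leaving out 1 library. In BTg against WT the ranges were -1.79 to 0.51 for Mki67, -1.59 to 0.0646 for Top2a, -1.22 to 0.24 for cell cycle, -2.08 to 0.32 for erythroid, -1.31 to 0.36 for mitochondrial and -0.38 to -0.00890 for nuclear respiratory chain genes, whose mean stayed below 0 while camera's direction turned. In BTg against CKO, Ccr7 ranged over -0.0788 to 1.17 and nuclear respiratory chain genes over -0.67 to 0.0238; Ccr7 was -0.16 without CKO replicate 1 and with a block, and with voom without CKO replicate 1 the lists for glycolysis and the nuclear respiratory chain were -0.0567, where camera's direction alone turned, and 0.20. Over the named genes, 3002 of the recomputed values kept their direction and side of the threshold, 40 passed it, 25 missed it with the same direction and 14 turned. This tally favours stability, since it leaves out the 8 genes withdrawn for turning sign, of whose values 511 kept direction and side and 40 turned. Over the called lists these were 1325 kept, 228 missed and 16 turned.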

Other observations

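Of the tests of explanations, only the one on gene length was chosen before its result was seen; the tests on neutrophils, genotype, the share of CD4 T cells, CKO replicate 1 alone, plasma or B cells, Tfh cells and the replicate number were chosen after. Between BTg and the libraries labelled CKO, all 6 measured gamma-delta T cell genes were lower in BTg (camera adjusted p = 1.4e-04; adjusted p = 0.343 with an estimated correlation), and 4 fell adjusted over the list alone; the list was not called without CKO replicate 2 (mean log2 difference -0.61). Of 5 CD8 T cell genes 3 fell and 1 rose adjusted over the list alone, with fry adjusted p = 0.00814 for a lower level, lost on recovered reads with voom (fry adjusted p = 0.246), and camera adjusted p = 0.0962. Single genes went both ways. Eomes and Gzmk, a transcription factor and a granzyme of memory T cells, fell, with log2 changes of -1.30 (SE 0.28) and -1.44 (SE 0.26) adjusted over their lists alone, at 0.0118 in the NK list and 0.00692 in the CD8 list. Prf1, which encodes perforin, and Klrd1, an NK receptor chain, rose, with 1.46 (SE 0.35) and 0.86 (SE 0.20), at 0.0118 and 0.0118. The NK list as a whole was not called (camera adjusted p = 0.354). In BTg against WT all 6 measured gamma-delta T cell genes were lower, with a median of -0.81 (camera adjusted p = 2.2e-08; adjusted p = 0.309 with an estimated correlation), and 2 fell adjusted over the list alone. The textbook Blimp-1 target list was lower in 11 of 15 (camera adjusted p = 6.5e-07; adjusted p = 0.309 with an estimated correlation), and genes next to Prdm1 on chromosome 10 were not called (adjusted p = 0.859 with an estimated correlation). In CKO against WT the textbook list had 8 members higher and 7 lower, and was not called (camera adjusted p = 0.434). Of its 15 measured members 14 stand in another list too, and in BTg against WT 1 fell adjusted over the list alone. Eomes, Gzmk, Prf1 and Klrd1 were chosen after their values were seen. The X-linked transcript Xist was between 40.8 and 97.1 FPKM in the 6 libraries.

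Neutrophil and plasma cell genes were high in CKO replicate 1. All 11 measured neutrophil list genes were at least 2-fold above the next library there, as neutrophils among the sorted cells may give; 0 of these genes are in another list and 5 reached 1 FPKM in both WT libraries. The median excess over WT in replicate 2 was 0.193 of that in replicate 1, so the libraries labelled CKO did not share an excess of like size. These values also define the pattern, so they are no separate test of a genotype effect. The neutrophil median exceeded the highest of the NK, gamma-delta and dendritic medians by 4.41 on the log2 scale. This cannot decide whether a lower share of CD4 T cells raised every other cell type alike. Of those lists, 5 of 6 NK, 3 of 6 gamma-delta and 3 of 5 dendritic genes reached 1 FPKM in both WT libraries and may not mark other cells. The monocyte, basophil and plasma cell lists, higher in replicate 1 than 2, and the erythroid list, lower there, were left out. If neutrophils were present, whether they came from the sort or from a difference in the tissue sampled stays open, and a CD4 gate would be expected to remove them.

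Tfh genes were higher in the libraries labelled CKO and lower in BTg. CKO replicate 1 alone is argued against as the whole cause, because the median log2 difference without it was 0.61. The Tfh excess of replicate 1 over replicate 2 was -0.0103 of the plasma cell excess. The Tfh median thus did not follow the plasma cell genes between these libraries. This cannot exclude plasma or B cells as a part of the source. Cd4 was lower in replicate 1, at 53.8 against 93.7 FPKM, and less T cell transcript could offset such a part. The B cell list was not used in this test, and neutrophils were not tested as a source of Tfh list reads. More Tfh cells and more transcript per cell cannot be told apart in bulk RNA, where either may give the median of 0.75. Because Prdm1 reads were not lower in these libraries, any link to Blimp-1 rests on their label.

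Libraries numbered 1 differed from those numbered 2 in every group. Mitochondrially encoded genes took 3.2, 1.93 and 2.31% of reads in the libraries numbered 1 of WT, CKO and BTg, against 1.25, 1.23 and 1.12% in those numbered 2, and ribosomal protein genes 16.2, 10.9 and 11.3% against 8.03, 7.13 and 7.1%. A batch shared by number stays open, since 7 of 9 medians of the mitochondrial, ribosomal and immediate early lists were higher in number 1; the immediate early list was not higher in WT or CKO, though Fos was 36, 64.1 and 62.8 against 10.4, 11.1 and 11.5 FPKM. For the ribosomal part, the excess over genes matched on length and level was 0.0344 of 0.58 in CKO and 0.07 of 0.57 in BTg. In WT 0.28 of 0.95 remained. Only the members of the list were kept out of the matched genes, so other ribosomal protein genes could be among them. A small excess therefore cannot decide whether a bias by gene length or level was the cause, and length and level were not separated. No biological explanation was tested, since the numbers carry no label of their own.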
